A study of Mus musculus with 8 samples.

How the data were processed

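Gene expression was measured by RNA sequencing in 8 libraries of mouse 3T3-L1 adipocytes, a fibroblast line that is turned into fat cells in culture. The labels put 4 libraries in a control group and 4 in a group overexpressing miR-690, called miR-690oe. Per the labels' protocols, RNA was isolated with a Zymo kit and libraries followed an Illumina protocol. The labels' protocols give the same miR-690 mimic treatment, at 5 pM, for every library, the control libraries included. What the control cells received is not given in the sources used here. The labels do not say whether the 4 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

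The submitters' processing notes name Trimmomatic 0.38, edgeR 3.20.9 and the mouse build mm10, with no role for each. The aligner, the read counter and the strand setting are not given in the sources used here. The deposited table held 10663 genes. The table was named as RPKM, but each of its 8 per-library columns summed to 1000000. Every value was also a whole multiple of a fixed step per column. The values deposited by the authors were therefore taken as CPM, scaled to a sum of 1000000 over the listed genes. The authors' group values C and T in the deposited table, also CPM, were not used. Per the file headers, the authors' deposited table also held a log2 fold change and an average log2 CPM per gene, a likelihood ratio, given here as the score LR, a p-value and a false discovery rate. The steps gave 29773446 to 38235522 reads per library, with 100% of the values whole within 0.1 read. These reads were used for depth and for the comparison of replicates, and no count model was fitted to them. The design fixed before the data were examined assumed RPKM. The same test was kept for CPM, since both are normalized values.

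The table listed symbols in capitals, and 15 entries held a date in place of a symbol, as a spreadsheet writes some gene names. These entries were kept in the tests and are not named. Of the 10663 entries, 10615 (99.5%) were matched to a gene of GENCODE release M21, which uses the same build as mm10, 140 of them through an older symbol. Transcript length and GC content came from the longest basic coding transcript, which need not be the one these cells use: for Npc2 it was 3299 nt and for Ctsl, a cathepsin gene chosen after its values were seen, 6168 nt. A wrong length misplaces a gene in the fits that remove the length trend. Of the entries, 10377 genes (97.3%) had an annotated 3' UTR. Genes that share reads with near-identical copies, such as ribosomal protein genes and Gapdh with their processed pseudogenes, and genes that overlap others, such as Zbed6, which lies inside Zc3h11a, are uncertain where the authors' counting could split them.

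Genes with a CPM of at least 0.5 in at least 4 of the 8 libraries were kept, which left 10658 genes. Values were analysed as log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a trend, a two-sided test and Benjamini-Hochberg adjustment with a threshold of 0.05. A log2 fold change is on the log2(CPM + 0.5) scale, miR-690oe over control, and understates changes of low genes. Of 30 gene lists written before the data were examined, 26 had at least 5 measured members and were tested with camera at a preset correlation of 0.01. Beside it stand camera with an estimated correlation, fry, and counts adjusted over the list alone. The 4 lists with too few measured members were the genes of the mitochondrial genome, macrophage markers, endothelial and blood cell markers, and replication-dependent histones.

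The rule for named genes was also fixed in advance. It took Nadk and the gene of the microRNA, Mir690. Among genes past the threshold with a mean CPM of at least 1 and no overlap between the groups, it took the 10 with the highest and the 10 with the lowest fold change. In each list it took up to 4 members with the lowest adjusted p. Any other gene named is marked as chosen after its values were seen.

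The labels name miR-690-5p and give no sequence. The mature mouse sequence used here, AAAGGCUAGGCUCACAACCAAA, was written from general knowledge before the data were examined, and every seed result depends on it. Matches to its seed (nucleotides 2 to 8, paired to TAGCCTT) were searched in the annotated 3' UTRs with Python 3.11.15. The median log2 fold change of genes with a match was compared with that of genes without a match, paired to them on 3' UTR length and mean level, by an exact permutation of the 70 label orders. The heptamer was also ranked among 15463 heptamers found in enough genes, in a regression on heptamer, 3' UTR length, transcript length, GC content and level.

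Alternatives covered the pseudocount, the filter, scaling, the variance model, array weights, a replicate block, the threshold, the set test, the site type, and leaving out each library. After the data were seen, fits were added in which a spline trend over transcript length and GC (4 degrees of freedom each) was removed from each library without use of its group, and the median of each list was set against 10000 random lists matched on length, GC and level. Pairs of libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 3.96 to 21.95, so all 8 were counted as separate. The steps were tested on simulated data for the comparison of miR-690oe with control. In 10660 simulated genes, limma recovered 18% of 50 genes changed by 0.2 on the log2 scale, 76% of 50 changed by 0.4, and 100% of those changed by 0.8 and by 1.5, with 10 false calls among 157 calls. The simulated noise was drawn separately for each gene, with no length trend. The rate of false calls therefore does not carry over to the real data.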

Results

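The transcriptome of 3T3-L1 adipocytes overexpressing miR-690 was compared with that of control adipocytes, with 4 libraries in each group. miR-690 is a mouse microRNA, and published work on it names the NAD kinase gene Nadk as its target. The control libraries held 29773446 to 33816227 reads and the miR-690oe libraries 31211349 to 38235522 reads over the listed genes, with a median of 1496 reads per gene and library. At this depth counting error was small for most listed genes, and 5 of them had under 10 reads in at least 1 library.

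Nadk, which makes NADP from NAD, was lower in miR-690oe adipocytes, at 203.8 ± 5.17 CPM against 223.7 ± 8.36 CPM in controls (SD, n = 4 each). Its log2 fold change was -0.13 ± 0.042 (SE, limma adjusted p = 0.0174), which is 0.912 of the control level, and the highest miR-690oe library lay below the lowest control library. Nadk2, which encodes the mitochondrial NAD kinase, rose, with a log2 fold change of 0.20 ± 0.054 (limma adjusted p = 0.00721), which was 0.08 (limma adjusted p = 0.252) with the length and GC trend removed. Nadk lies on chromosome 4 from 155562378 to 155591001 on the plus strand of mm10. Its annotated 3' UTR of 1526 nt held 1 match to the miR-690 seed, TAGCCTT, at position 90 of the 3' UTR (chromosome 4, 155589565 to 155589571), in the context CTGGCTGACCTAGCCTTGACAAACCAC. Without control replicate 2 the adjusted p of Nadk was 0.0695 at a log2 fold change of -0.12, and without control replicate 4 it was 0.0612 at -0.12, so the call rested on both libraries. With all 8 libraries and other scaling, filter or variance settings, the adjusted p ranged from 0.00769 with median-of-ratios scaling to 0.0363 without the variance trend. The gene of the microRNA, Mir690, was not among the listed genes, so its own level was not analysed here.

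**Figure D1:**
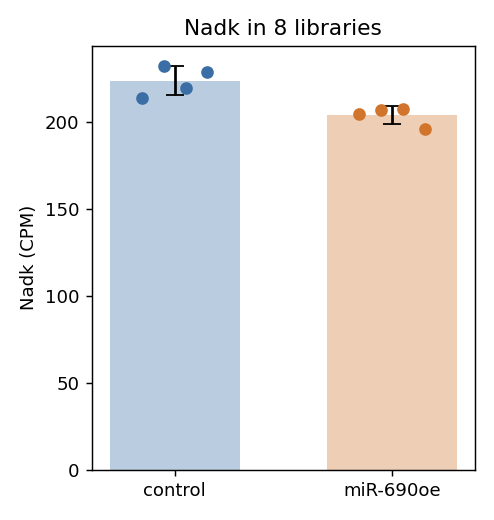
Nadk expression in CPM in the 4 control and 4 miR-690oe libraries. Points are libraries, bars are group means and error bars are SD; the means were 223.7 and 203.8 CPM.

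Among the genes that rose most in miR-690oe adipocytes, the histone lysine methyltransferase genes Kmt2d, Kmt2a and Kmt2c rose 1.87-fold, 1.78-fold and 1.67-fold, and Nfat5, a transcription factor of the osmotic stress response, rose 1.79-fold. Their log2 fold changes of 0.91, 0.83, 0.74 and 0.84 were 0.45, 0.38, 0.29 and 0.38 with the length and GC trend removed. Genes that fell most included Adh1, an alcohol dehydrogenase, at 0.75 of control, Gsta3, a glutathione S-transferase, at 0.756, and Endog, a mitochondrial nuclease, at 0.755; with the length and GC trend removed, Adh1 and Gsta3 had log2 fold changes of -0.29 and -0.35 (limma adjusted p = 0.00172 and 0.012) and Endog missed the threshold (-0.22, limma adjusted p = 0.0652). No called gene changed by more than 2-fold, and the 74 that changed by more than 1.5-fold were all higher in miR-690oe; with the length and GC trend removed, 10 called genes changed by more than 1.5-fold.

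Of 10658 genes tested, 4626 (43.4%) passed the threshold, 2773 higher and 1853 lower in miR-690oe. Their median absolute log2 fold change was 0.24, and at an unadjusted p under 0.05 the count was 5421. The values of the 2 groups did not overlap for 4083 genes (38.3%), where chance gives 2.86%. Higher genes made up 59.9% of the calls, and 46.4% after quantile normalization. The authors' deposited table listed 4835 genes at a false discovery rate under 0.05, 2634 higher and 2201 lower, and 4471 genes were called in the same direction in both.

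Kmt2d, on chromosome 15 from 98831669 to 98871204, stood at 34.67 ± 2.85 CPM in controls and 65.9 ± 11.03 CPM in miR-690oe (log2 fold change 0.91 ± 0.091, limma adjusted p = 4.14e-06). Log2 fold changes were 0.84 for Nfat5 and 0.83 for Kmt2a. Zbed6, a transcription factor gene inside Zc3h11a, rose by 0.78, and Zfhx4, a zinc finger homeobox gene, by 0.78. Tmem245 rose by 0.77, Lpp, a focal adhesion protein gene, by 0.75, and both Mdn1, needed for assembly of the large ribosomal subunit, and Dst, a cytoskeletal linker, by 0.74. In the fit with the trend removed, Zbed6 had 0.57, Zfhx4 0.32, Lpp 0.26, Mdn1 0.25 and Dst 0.20, and among the genes that fell Gm5617 had -0.23, Tmem160 -0.25 and Clec11a -0.39. Among the lowest, S100g, a small calcium-binding protein gene, had a log2 fold change of -0.50 at 2.33 CPM in controls. Gm5617 fell to 0.718 of control, Tmem160 to 0.728, Crip1 to 0.738 and 2200002D01Rik to 0.744. Clec11a, a secreted lectin, had 0.758 of the control level. H1fx, a linker histone, had 0.759 (adjusted p = 0.0268), a call that was lost without control replicate 2 (adjusted p = 0.061), control replicate 3 (0.0956), miR-690oe replicate 1 (0.0785) or miR-690oe replicate 4 (0.0571), and with array weights or quantile normalization. Tmem245 (limma adjusted p = 0.0572), S100g (0.184), Crip1 (0.231), 2200002D01Rik (0.107) and H1fx (0.254) missed the threshold with the length and GC trend removed, at log2 fold changes of 0.27, -0.31, -0.20, -0.28 and -0.24.

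**Figure D2:**
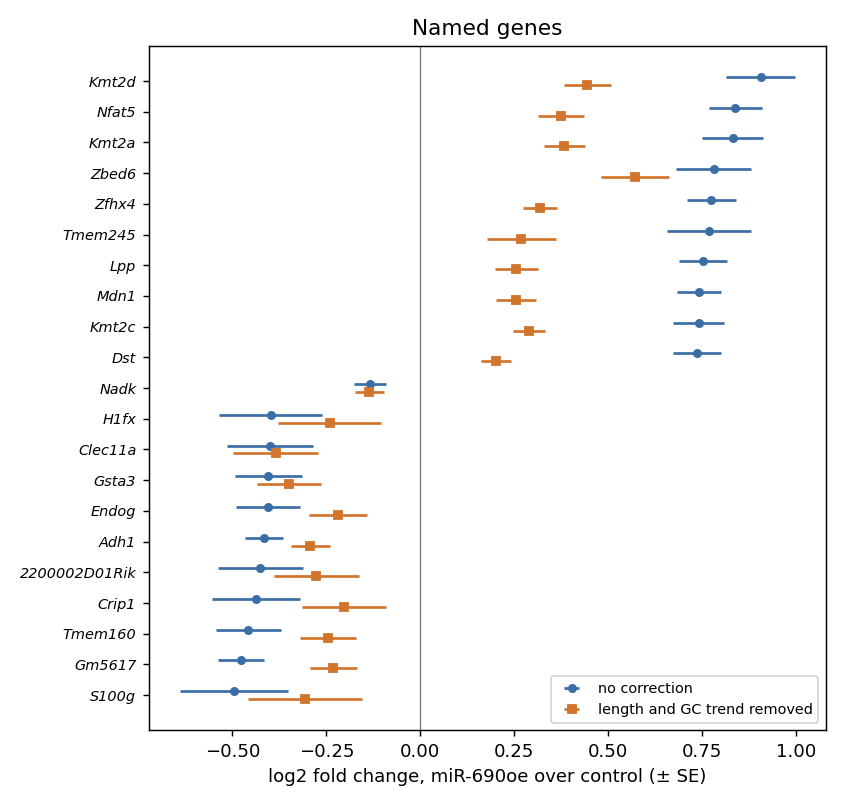
Log2 fold change of miR-690oe over control for Nadk and the 20 genes with the highest and lowest fold change. Points are limma estimates and bars are SE, in blue without correction and in orange with the length and GC trend removed; Kmt2d went from 0.91 to 0.45 and Nadk from -0.13 to -0.14.

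Cytosolic ribosomal protein genes and nuclear-encoded genes of oxidative phosphorylation were lower in miR-690oe. Of 76 cytosolic ribosomal protein genes, 75 fell and none rose, with the same counts adjusted over the list alone. Rps10 stood at 0.776 of control, Rps15 at 0.771, Rps21 at 0.794 and Fau at 0.774. The median log2 fold change of the list was -0.27 (camera adjusted p = 4.25e-26, and adjusted p = 0.556 with an estimated correlation). Of 48 nuclear-encoded genes of oxidative phosphorylation 44 fell, 45 adjusted over the list alone, with Cox6a1 at 0.791, Atp5o at 0.795, Cox4i1 at 0.796 and Ndufb10 at 0.80 of control. Their median was -0.22 (camera adjusted p = 6.55e-15, and adjusted p = 0.592 with an estimated correlation). Removal of the length and GC trend left 28 ribosomal protein genes lower and 1 higher, and 9 respiratory genes lower, with camera adjusted p of 1.05e-10 and 7.51e-05 (adjusted p = 0.78 and 0.784 with an estimated correlation). Rps21, Cox6a1, Cox4i1 and Ndufb10 missed the threshold in that fit (limma adjusted p = 0.0982, 0.0687, 0.0756 and 0.0635), and Rps10, Rps15, Fau and Atp5o had log2 fold changes of -0.16, -0.13, -0.15 and -0.13, against -0.37, -0.38, -0.37 and -0.33 without removal.

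Genes of insulin signalling, the pathway from the insulin receptor to glucose uptake, rose more often than they fell. Of 31 members 16 rose and 3 fell, with the same counts adjusted over the list alone. The insulin receptor gene Insr rose 1.5-fold, its substrate Irs1 1.43-fold, Gsk3b, which phosphorylates glycogen synthase, 1.40-fold, and Pik3r1, a regulatory subunit of phosphoinositide kinase, 1.38-fold. The median log2 fold change was 0.16 (camera adjusted p = 0.00905, and adjusted p = 0.516 with an estimated correlation). Slc2a4, the insulin-regulated glucose transporter, chosen after its values were seen, had a log2 fold change of 0.01 (limma adjusted p = 0.929). With the length and GC trend removed, 8 members of the list were higher and 2 lower, and the camera adjusted p was 0.311. The log2 fold changes of Insr, Irs1, Gsk3b and Pik3r1 went from 0.58, 0.51, 0.49 and 0.47 to 0.24, 0.21, 0.17 and 0.18.

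Genes of the microRNA machinery also rose. Of 18 members 13 rose and 1 fell, and 14 rose adjusted over the list alone. Tnrc6b and Tnrc6a, partners of Argonaute, rose 1.65-fold and 1.42-fold, the decapping enzyme gene Dcp2 1.37-fold and Dicer1, which cuts microRNA precursors, 1.29-fold. The median was 0.32 (camera adjusted p = 0.00013, and adjusted p = 0.516 with an estimated correlation), and with the length and GC trend removed 4 members were higher, the camera adjusted p was 0.0663, and Dcp2 and Dicer1 missed the threshold (limma adjusted p = 0.0807 and 0.863). Tnrc6b went from 0.72 to 0.22 and Tnrc6a from 0.50 to 0.20 in log2 fold change. Of 7 thermogenic genes 4 rose, with the same counts adjusted over the list alone. Ppargc1b, a coactivator of mitochondrial genes, rose 1.32-fold, Ebf2 1.30-fold and Gk 1.22-fold. Ppargc1a, a related coactivator, also had 1.22-fold (limma adjusted p = 0.0207), a call lost without control replicate 4 (0.0508) or miR-690oe replicate 2 (0.083). The list's camera adjusted p was 0.0308 (adjusted p = 0.516 with an estimated correlation); it was 0.0577 without control replicate 3, and 0.0663 with the length and GC trend removed, where Ppargc1b was higher and Ebf2, Gk and Ppargc1a missed the threshold (limma adjusted p = 0.0966, 0.237 and 0.989).

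Autophagy and lysosome genes fell more often than they rose, 15 against 4 of 32, with the same counts adjusted over the list alone. Atp6v0d1, a subunit of the lysosomal proton pump, stood at 0.812 of control, Npc2, which carries cholesterol out of lysosomes, at 0.825, Map1lc3a at 0.789 and the hexosaminidase gene Hexa at 0.865. The median was -0.10 (camera adjusted p = 0.00327, and adjusted p = 0.592 with an estimated correlation). Removal of the length and GC trend left 8 lower and 1 higher, with a camera adjusted p of 0.00388 (adjusted p = 0.784 with an estimated correlation), where the length of a member is that of its longest annotated transcript, 3299 nt for Npc2. Among antioxidant and NRF2 target genes, 14 of 29 fell and 3 rose, 15 and 3 adjusted over the list alone. Gpx1, Sod1 and Gpx4, which remove peroxides and superoxide, stood at 0.784, 0.831 and 0.821 of control, while the cystine transporter gene Slc7a11 rose 1.56-fold. The camera adjusted p was 0.00368 (adjusted p = 0.592 with an estimated correlation), and 0.163 with the length and GC trend removed, where 1 member was higher and 7 lower. Hexa, Sod1 and Gpx4 missed the threshold in that fit (limma adjusted p = 0.107, 0.419 and 0.162). The log2 fold changes of Atp6v0d1, Map1lc3a, Gpx1 and Slc7a11 went from -0.30, -0.34, -0.35 and 0.64 to -0.18, -0.16, -0.17 and 0.26.

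Of 17 glycolysis genes 11 fell and 2 rose, 12 and 2 adjusted over the list alone. Tpi1, Gapdh and Eno3 stood at 0.834, 0.855 and 0.812 of control, and the hexokinase gene Hk2 rose 1.31-fold. The camera adjusted p was 0.00647 (adjusted p = 0.592 with an estimated correlation). Of 21 genes of the TCA cycle 8 fell, the same adjusted over the list alone, with Sdhb at 0.831 and Idh2 at 0.871 (camera adjusted p = 0.0135, and adjusted p = 0.867 with an estimated correlation). Of 23 genes of fatty acid oxidation 9 fell and 1 rose, 10 and 1 adjusted over the list alone, with Acaa2 at 0.831 and Etfb at 0.828 (camera adjusted p = 0.0192, and adjusted p = 0.867 with an estimated correlation). The call of the TCA cycle was lost without control replicate 2 (adjusted p = 0.0583) and after quantile normalization (0.213), and that of fatty acid oxidation without control replicate 2 (0.0531) or miR-690oe replicate 3 (0.0504). With the length and GC trend removed, the camera adjusted p was 0.0178 for glycolysis (adjusted p = 0.784 with an estimated correlation), 0.193 for the TCA cycle and 0.348 for fatty acid oxidation. In that fit 3 glycolysis genes were lower and 1 higher, 1 TCA cycle gene was lower and 0 higher, and 4 genes of fatty acid oxidation were lower and 1 higher. Gapdh, Eno3, Sdhb, Idh2 and Etfb missed the threshold there (limma adjusted p = 0.17, 0.0865, 0.131, 0.234 and 0.226), and Tpi1, Hk2 and Acaa2 went from log2 fold changes of -0.26, 0.39 and -0.27 to -0.14, 0.23 and -0.14.

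Markers of the differentiated fat cell were not called as a list. Of 27 markers 5 fell and 1 rose, and none passed adjusted over the list alone or with the length and GC trend removed (camera adjusted p = 0.108). Agpat2, an enzyme of triglyceride synthesis, stood at 0.838 of control (limma adjusted p = 0.0142, 0.0565 without control replicate 2, and 0.353 with the length and GC trend removed). The list was called without control replicate 3 (adjusted p = 0.0182) or miR-690oe replicate 2 (0.00302), and had an adjusted p of 0.867 with an estimated correlation and all 8 libraries. Fibroblast and preadipocyte markers went both ways, 4 higher and 4 lower of 23, with 4 and 3 adjusted over the list alone (camera adjusted p = 0.475). Prrx1, a mesenchymal transcription factor gene, rose 1.25-fold and S100a4 stood at 0.823 of control; with the length and GC trend removed both missed the threshold (limma adjusted p = 0.585 and 0.483), and 1 member of the list was higher and 2 lower. Of the lists with too few measured members to test, the genes of the mitochondrial genome had 0 measured. Of 3 macrophage markers, Lyz2 and Cd14 had log2 fold changes of -0.26 and -0.19 (limma adjusted p = 0.0476 and 0.031) and Cd68 had 0.02 (0.939). The endothelial marker Egfl7 had -0.08 (limma adjusted p = 0.608), and of 4 histone genes Hist1h1c had -0.20 (limma adjusted p = 0.00299).

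The other lists were not called by camera. Of the 18 genes of NAD metabolism 3 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.498). Beside Nadk, Nnmt, which methylates nicotinamide, stood at 0.841 of control and Pnp at 0.87, and the aldehyde oxidase gene Aox1 rose 1.23-fold. Lipogenesis had 7 higher and 3 lower of 24, the same adjusted over the list alone, with Elovl6, a fatty acid elongase gene, up 1.35-fold (camera adjusted p = 0.829), and cholesterol synthesis had 8 higher and 6 lower of 22, or 8 and 7 adjusted over the list alone, with Hmgcs1 up 1.24-fold and Ebp at 0.826 of control (camera adjusted p = 0.762, direction down, although the median was 0.003 and the mean 0.015). Lipolysis had 3 higher and 1 lower of 13, or 2 and 0 adjusted over the list alone, with Npr3, a natriuretic peptide receptor gene, up 1.28-fold (camera adjusted p = 0.498). Extracellular matrix genes had 14 higher and 3 lower of 35, the same adjusted over the list alone, led by Thbs1, which rose 1.56-fold, and the collagen gene Col12a1, which rose 1.5-fold (camera adjusted p = 0.166). That list was called after quantile normalization (adjusted p = 0.00614) and without miR-690oe replicate 2 (0.02), and had an adjusted p of 0.867 with an estimated correlation and all 8 libraries. With the length and GC trend removed it had 1 member higher and 2 lower, with a median of 0.008 (camera adjusted p = 0.764), and Col12a1 missed the threshold (limma adjusted p = 0.0704). In the same fit lipogenesis had 0 higher and 2 lower, its median going from 0.055 (-0.006 to 0.087 with 1 library left out) to -0.061 (camera adjusted p = 0.296), and Elovl6 missed the threshold (limma adjusted p = 0.0676). NAD metabolism then had 1 higher and 2 lower, cholesterol synthesis 1 higher and 2 lower, and lipolysis 0 higher and 1 lower, and Nnmt, Aox1 and Npr3 missed the threshold (limma adjusted p = 0.108, 0.0612 and 0.413). Ebp went from a log2 fold change of -0.28 to -0.18.

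Immediate early genes, which respond within minutes to stimulation, had 9 higher and 1 lower of 21, the same adjusted over the list alone. Egr1 rose 1.38-fold, Klf6 1.21-fold, Klf10 1.13-fold and Jun 1.31-fold. Their median log2 fold change was 0.21 (camera adjusted p = 0.0697, and adjusted p = 0.867 with an estimated correlation). The list was called without control replicate 1 (adjusted p = 0.0088), without miR-690oe replicate 1 (0.00742), with array weights (0.029), after quantile normalization (0.0491) and with the length and GC trend removed (1.54e-06, or 0.78 with an estimated correlation), where 8 members were higher and 0 lower and Klf6 missed the threshold (limma adjusted p = 0.054).

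For the remaining lists the counts were the same adjusted over the list alone, except the last. Unfolded protein response genes had 10 higher and 2 lower of 25, with Canx up 1.18-fold (camera adjusted p = 0.17, 0.0491 after quantile normalization and 0.0478 without miR-690oe replicate 1, and adjusted p = 0.867 with an estimated correlation). NF-kB targets had 8 higher and 3 lower of 30, with Nfkbiz up 1.29-fold (camera adjusted p = 0.828). Interferon-stimulated genes had 5 higher and 7 lower of 40, with Bst2 at 0.854 of control and Gbp7 up 1.27-fold (camera adjusted p = 0.453, direction down, although the median was 0.03). Cell cycle genes had 6 higher and 8 lower of 37, with Mki67 up 1.41-fold and Tk1 at 0.826 (camera adjusted p = 0.409, median -0.025, or -0.049 to 0.005 with 1 library left out, mean 0.007). TGF-beta targets had 3 higher of 14, with Skil up 1.45-fold (camera adjusted p = 0.78). Targets of p53 had 7 higher and 3 lower of 24, with Zmat3 up 1.21-fold (camera adjusted p = 0.828). Hypoxia targets had 5 higher and 1 lower of 22, with Vegfa up 1.22-fold (camera adjusted p = 0.762). Genes of the integrated stress response had 4 higher and 6 lower of 32, or 4 and 4 adjusted over the list alone, with Slc7a1 up 1.25-fold and Sars at 0.864 (camera adjusted p = 0.296, median -0.063, mean 0.009). After removal of the length and GC trend, the unfolded protein response had 1 higher and 1 lower (camera adjusted p = 0.195) and cell cycle genes 0 higher and 7 lower (0.163). NF-kB targets had 3 higher and 3 lower in that fit, interferon-stimulated genes 0 and 1, TGF-beta targets 1 and 0, p53 targets 2 and 0, hypoxia targets 2 and 1, and the integrated stress response 3 and 3. Canx, Mki67, Bst2, Gbp7, Zmat3 and Slc7a1 missed the threshold there (limma adjusted p = 0.194, 0.085, 0.854, 0.402, 0.894 and 0.292), and Skil and Tk1 went from log2 fold changes of 0.54 and -0.28 to 0.24 and -0.13. In all, 10 of 26 lists were called by camera, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 9 by fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Of the lists called by camera, fry did not call the TCA cycle (adjusted p = 0.165) or fatty acid oxidation (0.0883), and it called the unfolded protein response (0.0406), which camera did not.

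**Figure D3:**
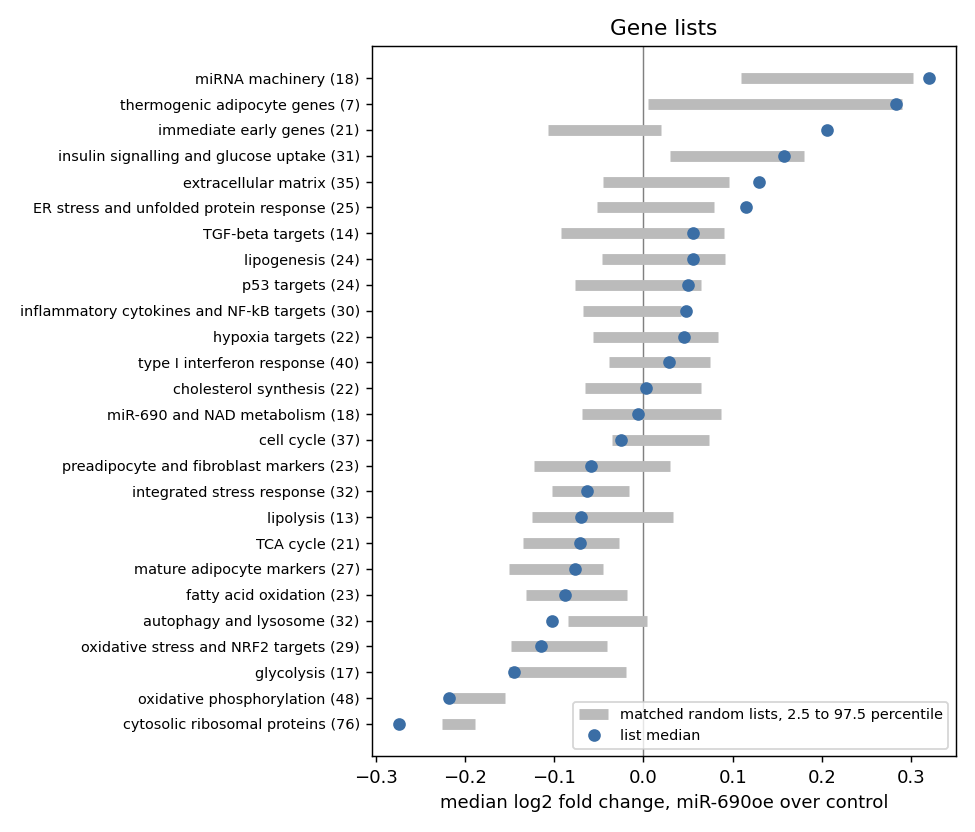
Median log2 fold change of each gene list, miR-690oe over control, as blue points, with the number of members in parentheses. Grey bars leave out the lowest and the highest 2.5% of 10000 random lists matched on transcript length, GC and level; ribosomal protein genes lay at -0.27 and immediate early genes at 0.21, both outside their bars.

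Transcript length ran with the fold changes over the transcriptome. In the shortest of 5 length groups, from 174 to 1755 nt, which held 66 ribosomal protein genes, the 2122 genes had a median log2 fold change of -0.17, with 1081 lower and 21 higher. In the longest group, from 5072 nt up, which held Kmt2d, Nfat5 and Insr, they had a median of 0.26, with 1581 higher and 23 lower. Across the 10610 genes with a length, Spearman's correlation of log2 fold change with length was 0.73 and Pearson's was 0.72, where genes are not independent replicates. The slope of log2 level on log2 length, fitted together with GC and relative to the mean of the 8 libraries, was -0.0715 ± 0.012 in controls and 0.0715 ± 0.0418 in miR-690oe (SD, n = 4 each; exact permutation p = 0.0286, two-sided, the smallest that 70 label orders allow).

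With the trend over length and GC removed, 1705 of 10610 genes passed the threshold, 766 higher and 939 lower. Of the 4611 called genes with a length, 1095 (23.7%) kept their call and direction and 46 were called in the opposite direction. Of the 121 genes other than Nadk taken by the naming rule, 50 kept call and direction, 32 of them with a log2 fold change more than 1.5 times smaller. Another 66 kept their sign but missed the threshold, Nadk2, Dicer1, Sod1 and Prrx1 among them. The other 5 turned sign, and of these only Vldlr passed the threshold (-0.16, limma adjusted p = 0.0156). Nadk kept a log2 fold change of -0.14 ± 0.039 (limma adjusted p = 0.0275), but missed the threshold with a replicate block added (limma adjusted p = 0.0562). Kmt2d, Kmt2a and Nfat5 had 0.45, 0.38 and 0.38.

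**Figure D4:**
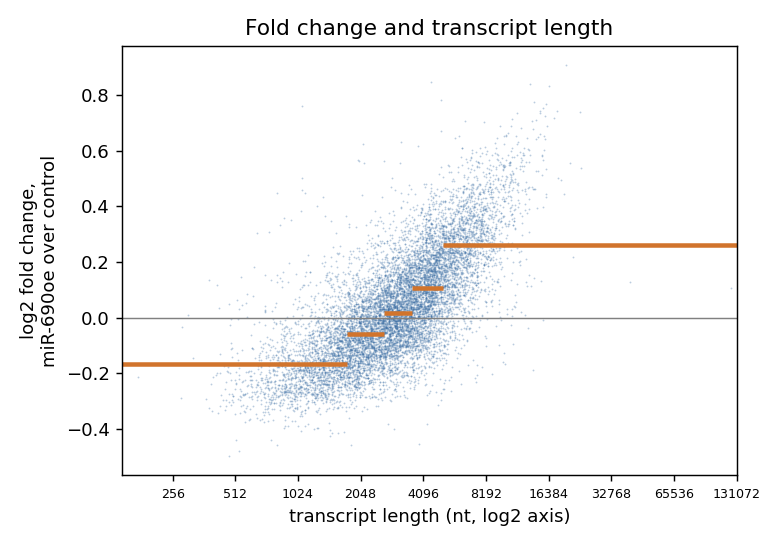
Log2 fold change of miR-690oe over control against transcript length in nt on a log2 axis, with a point for each of 10610 genes. Orange lines are medians of the 5 length groups of equal size and rise from -0.17 in the shortest to 0.26 in the longest.

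Genes with a match to the miR-690 seed were compared with genes without a match, to ask whether predicted targets were lower as a group. A match to the heptamer TAGCCTT was present in the 3' UTR of 1250 of 10375 genes searched, Nadk among them. Their median log2 fold change was 0.094, against 0.12 in 1250 genes matched on 3' UTR length and level, a difference of -0.0259 that did not pass the test (exact permutation p = 0.0571, two-sided). The matched genes lacked the heptamer but could hold the shorter hexamer site. Genes with the heptamer had longer 3' UTRs, with a median of 2552.5 nt against 1024 nt, and compared with all genes without a match they were higher by 0.0854 (exact permutation p = 0.0286, two-sided, the smallest possible). The shift was -0.0076 for the 228 genes with an octamer site, whose matched genes lacked the octamer but could hold the heptamer. For the 4450 genes with a hexamer site it was 0.0448. Each matched gene was used once. The closeness of the 3' UTR lengths is given only for the heptamer (medians 2552.5 and 2556 nt). The hexamer shift may therefore hold a difference in 3' UTR length. With 1 library left out, the exact permutation p over 35 label orders was 0.0286 without control replicate 1 (-0.0369) and 0.0571 to 0.2 without each of the other 7, such as 0.2 without miR-690oe replicate 4 (-0.0192). With the length and GC trend removed the shift was -0.0161 (exact permutation p = 0.4), and with length alone removed -0.0132 (exact permutation p = 0.457).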

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

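The tests of library depth and of the unequal length of matched genes, the length and GC fits and the matched random lists were chosen only after the results were seen.

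Gm1821, a transcribed processed pseudogene on chromosome 14 from 46084028 to 46085000, lay outside the tests because too few libraries passed the filter. It stood at 7.081 CPM (221 reads) in miR-690oe replicate 4 and 6.25 CPM (239 reads) in miR-690oe replicate 1. The other miR-690oe libraries had 3 and 1 reads, and the controls 1 to 4 reads, at most 0.118 CPM. The authors' deposited table gave it a log2 fold change of 5.18 and a false discovery rate of 1.23e-14.

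In 300 groups of 4 libraries, 14 (4.7%) held a library far from the other 3 by Dixon's ratio, and chance gives about 5%. In miR-690oe, Gsk3b was low in replicate 4 at 123.9 CPM, Thrsp high in replicate 2 at 138.1, Plin2 low in replicate 1 at 221.1, Stard4 low in replicate 4 at 34.86, Cox6a1 high in replicate 4 at 363.7, Gk low in replicate 1 at 21.66, Bst2 high in replicate 1 at 43.02 and Tk1 high in replicate 4 at 77.73. In controls, Lpp was high at 100.1 CPM, Slc7a11 at 11.54 and Jun at 42.23, each in replicate 1, Gsta3 at 19.84 in replicate 4 and Polk at 28.21 in replicate 3. The mean log2 level of TGF-beta targets was low in miR-690oe replicate 3, at 4.701.

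Genes with longer transcripts were higher and genes with shorter ones lower in miR-690oe. Library depth as the whole cause was argued against: with total reads in the fit, the group difference of the length slopes was 0.1135 ± 0.0169 (SE), against 0.143 without them. A length bias that varies between libraries, from RNA integrity or library preparation, stays open. The miR-690oe slopes ran from 0.0316 in replicate 4 to 0.1295 in replicate 1, with an SD of 0.0418 against 0.012 in controls. The SD of the slopes within groups was 0.215 of the difference between the group means, between the bounds set beforehand, and no label names a batch, so this bias and an effect of miR-690 cannot be told apart. Of the 4611 called genes with a length, 1095 (23.7%) kept call and direction without the trend, also between the bounds set. Most calls were thus lost or turned when the trend was removed. Length and GC accounted for 58.5% of the variance of the log2 fold changes over genes. What caused the trend stays undecided.

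Ribosomal protein genes were lower in miR-690oe than genes matched on length, GC and level. Their median of -0.274 lay below the 2.5 percentile of the matched lists, -0.226. The matched lists were drawn gene by gene, so their range leaves out the correlation among ribosomal protein genes and the spread between libraries. With an estimated correlation the list was not called (camera adjusted p = 0.556, and 0.78 with the trend removed). The nearest genes were longer, with a median of 1169 nt against 925.5 nt, but with the trend removed first the median of -0.095 still lay below the matched 2.5 percentile of -0.069. The matched genes also had a lower median log2 level, 8.59 against 9.36, so a trend over level is left open, as are reads shared with pseudogenes and a biological effect of miR-690.

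Of the 35 splits of the 8 libraries, only the real one gave as many as 4626 called genes, and the highest other split gave 6. A share of 1 in 35 is the smallest these splits allow. Every other split mixes the 2 groups, so the count cannot tell a technical difference between the groups from an effect of miR-690. For the lists, 18 of the 35 splits gave as many called lists as the real 10, and the highest other gave 18. The camera calls at a preset correlation therefore cannot be set apart from chance by their number.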

How the results depend on the processing

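The fits with the length or GC trend removed and the matched random lists were chosen after seeing the data. The count of changed genes stayed within 1.5 times 4626 under the planned settings, except 3047 at an adjusted p under 0.01. With the length and GC trend removed it was 1705, with length alone 1858, and with length, GC and a replicate block 1202. Called lists fell from 10 to 0 with an estimated correlation and to 5 in each of those 3 fits. Nadk ranged from -0.155 to -0.116 with 1 library left out, and missed the threshold with length, GC and block (-0.135, adjusted p = 0.0562). The seed shift ranged from -0.0369 to -0.0192 with 1 library left out, was -0.0161 (exact permutation p = 0.4) with length and GC removed, -0.0132 (0.457) with length alone and -0.0161 (0.625) with the block added, and was 0.0854 against all genes without a site, a group with shorter 3' UTRs. With length and GC removed, with or without the block, the sign turned for Pde3b (-0.053), Dnajc3 (-0.001), Vldlr (-0.16), Zmat3 (-0.011) and Bax (0.006); with length alone, for Plin4 (-0.013), Gpam (-0.002), Pde3b (-0.022), Ltbp2 (-0.055), Trim25 (-0.007), Vldlr (-0.131) and Zmat3 (-0.014). The removed trend moved these values by construction. With 1 library left out, 10 of the 121 named genes other than Nadk lost their call at least once and none turned. The replicate numbers did not pair the libraries (correlations of deviations -0.30, 0.31, -0.10 and -0.33, and 1 library correlated best with its own number); with the replicate block 4209 genes and 11 lists were called, the mature adipocyte markers among them (adjusted p = 0.042), the adjusted p of Nadk was 0.0361 and the exact permutation p of the seed shift was 0.25. With the block, the exact permutation of the seed shift had only 16 label orders, too few for a p under 0.05. Its p of 0.25 and 0.625 therefore could not have passed. In the 4 added settings 80 of the 121 named genes kept their sign but missed the threshold at least once. In the same settings 9 turned sign at least once, and some genes are in both counts. Depth limited few of the listed genes, since 5 had under 10 reads in at least 1 library. Each listed gene had at least 113 reads over the 8 libraries, so genes with fewer reads are not covered.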

Other observations

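The fits with the length and GC trend removed, the matched lists and the heptamer regression with length and GC terms were chosen only after the data were seen.

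Against random lists matched on transcript length, GC and level, 8 of 26 lists lay in the lowest or the highest 2.5%. The random lists were drawn gene by gene, so their range leaves out the correlation among the genes of a list. Immediate early genes stood at the 100th percentile, with a median log2 fold change of 0.21 where matched lists had -0.04, and with the trend removed their median was 0.22 with 8 members higher and 0 lower. Unfolded protein response genes stood at percentile 99.86, extracellular matrix genes at 99.95 and NF-kB targets at 98.48, and with the trend removed first at 99.77, 99.33 and 99.41. Their medians in that fit were 0.044, 0.008 and 0.048, with camera adjusted p of 0.195, 0.764 and 0.311, so these lists lay above their matched lists without being called. For extracellular matrix genes the matched genes were shorter, with a median of 4099 nt against 4741 nt. Their median log2 level was also lower, 8.49 against 9.2, so a trend over level is left open there. Thermogenic genes stood at percentile 96.06, inside the range, and at 98.08 with the trend removed first, with a median of 0.174 (camera adjusted p = 0.0663). Autophagy and lysosome genes stood at 0.46, and at 0 with the trend removed first, where matching used the longest annotated transcript of each gene. MicroRNA machinery stood at 99.09 and oxidative phosphorylation at 0.97, but with the trend removed first both lay inside the matched range, at 89.35 and 4.77. Insulin signalling lay inside its matched range both ways, at percentiles 90.51 and 94.02.

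In a regression across genes with length, GC and level, genes with the miR-690 seed heptamer were lower by an effect of -0.0182 ± 0.0036 (SE over genes, which are not replicates), rank 83 of 15463 heptamers (0.5%), against 0.0807 ± 0.0059 and rank 9230 without those terms. Across libraries the shift with the length and GC trend removed did not pass (-0.0161, exact permutation p = 0.4), so the pattern is a hypothesis. The lowest heptamer was GAACTCA, found in SINE B1 repeats. Without genes holding GAACTCA, the effect of the seed heptamer was -0.0168 ± 0.0041. The reverse complement of GAACTCA, TGAGTTC, ranked 3 with an effect of -0.0213. Genes that held TGAGTTC but not GAACTCA stayed in that fit, so repeats as the cause stay open. Direct repression stays open: genes with 2 or more sites differed from genes with 1 by -0.0164 ± 0.0098. That is more than the SE set as its bound, but less than the 2 SE asked of the other explanations. In the same regression across genes, the 228 genes with the octamer site had an effect of -0.0304 ± 0.0077 against all genes without it. GAACTCA was present in 27.9% of genes with the seed heptamer and 14.5% of the others. These shares are not adjusted for 3' UTR length, which had a median of 2552.5 nt against 1024 nt. Since GAACTCA was more frequent in genes with the seed heptamer, the difference by number of sites does not tell repression from repeats. Sequence shared by both strands stays open too, since the reverse complement AAGGCTA, which cannot pair with the seed, had -0.0134 ± 0.0041, and the site differed from it by -0.0046 ± 0.0055.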
